A study of Mus musculus with 21 samples.

How the data were processed

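Total RNA from whole mouse uterus was measured on 21 single-colour oligonucleotide arrays, the A subunit of an Affymetrix mouse set with 6584 probe sets. The deposited table gives 1 intensity per probe set and array, and the authors' software, scaling target and detection calls are not given in the sources used here. The deposited intensity values are linear and never negative, and the mean between the 2nd and 98th percentile of each array was 1498.97 to 1499.21. Because these trimmed means lay within 5% of each other, the values were used as deposited, without further scaling. All 21 arrays were used, in 10 groups of 2 (EE and vehicle at 5 schedules) and 1 array at 0 h, as the labels name them.

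The 55 control probe sets were set aside, which left 6529. A floor was set at the median over arrays of the 30th percentile (249.5 signal units), lower values were raised to it and all values were taken to log2. The 5807 probe sets above the floor on at least 2 of the 21 arrays were tested. Of the 6529 probe sets, 5541 had 1 gene symbol in the platform annotation, 197 had several and 791 had none. Symbols were updated through Entrez gene identifiers with RefSeq gene names of assembly GRCm38.p6 for 5532 probe sets and kept for 9. The tested probe sets with 1 symbol were 5044, for 4379 genes. Some genes that are usual markers of the uterine response were not analysed here, because no probe set of a single symbol was measured for them. Probe sets called of shared sequence here are those whose design name ends in _f_at, _r_at or _i_at. That ending does not always mean sequence common to several transcripts. Names ending in _s_at were not marked, so an unmarked probe set can also share sequence.

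Differences were tested with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean for each of the 11 groups, 10 residual degrees of freedom and an empirical Bayes prior of 3.10 degrees of freedom. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested in each contrast, and the threshold was an adjusted p under 0.05. The contrasts were EE against vehicle at each of the 5 schedules, the EE change at 3x24h minus that at 24 h, a moderated F test for a difference among the 5 EE changes and one among the 5 vehicle groups. Moderated F tests and the estimate of spread used all groups of 2. The 0 h array has no replicate and gave values only. When leaving out 1 array left a group with 1 array, that array was assumed to vary like the other groups.

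Before the data were examined, 38 gene lists with 1354 genes were written from general knowledge of the uterus, of oestrogen action and of cell types a whole uterus holds. Lists with at least 5 measured genes, 37 of the 38, were tested with camera (limma) at an inter-gene correlation of 0.01, with 1 probe set per gene, that of the highest mean. The p-values were adjusted over 185 tests, 37 lists at 5 schedules, and a second run with a correlation estimated from the data is reported beside each call. That run also takes its degrees of freedom from the residuals, so a call lost there is not due to correlation alone. For glycolysis at 24 h the estimated correlation was -0.0499, below 0.01, yet the camera p rose from 0.00221 to 0.00978. Of the 37 lists, 18 passed at 1 or more schedules and 19 at none, among which the smallest adjusted p was 0.074. For the difference of 3x24h and 24 h the adjustment was over 37 lists.

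Also before the data were examined, the comparisons, the tests, the floor, the filter and the rule for named genes were fixed. At each schedule the rule took, from probe sets that passed with no overlap between the EE and vehicle arrays, the 8 largest rises and the 5 largest falls with 1 symbol. It added up to 4 members that passed from each list past camera, up to 3 members with the smallest adjusted p from a list described without passing, and the 6 largest differences each way between 3x24h and 24 h. The rule also fixed a set of genes to be named in any case where measured, of which Muc1 and Vegfa are reported here. Not every gene that the rule took is described below. Genes named outside this rule are marked as named after their values were seen. Folds are ratios of means of log2 values, and "at least" marks a fold against a group whose arrays were both at or below the floor. A fold against a group with only 1 array below the floor carries no such mark and can also be too small.

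The counts, the gene lists and the named genes were recomputed with another normalisation, with other floors and filters, with a pseudocount in place of the floor, with a replicate block, with an intensity trend and with each array left out in turn. Array weights were run on the counts and the named genes but not on the lists, and all 10 vehicle arrays as control and the 4 arrays of a schedule alone on the counts and named genes of EE against vehicle. Covariates for RNA quality, the omission of arrays with 3′ biased RNA and the 2 vehicle 3x24h arrays as control for every EE group were added after the data were examined. Two-sided exact permutation tests over 184756 splits compared hybridisation controls between 10 EE and 10 vehicle arrays.

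The steps were tested on simulated data of the same size, for EE against vehicle at 8 h over 5807 probe sets. Of 25 probe sets raised at each size, 32% were recovered at a log2 change of 1, 100% at 2, 96% at 3 and 100% at 4. For 25 lowered at each size these shares were 12%, 68%, 52% and 68%. Of 135 probe sets called, 3 (2.22%) had not been changed. With no change simulated, limma called 0 probe sets at 8 h and 0 in both F tests, and camera passed 0 of 185 lists. The simulated noise was independent for each probe set and array, so this result does not cover correlated genes or array effects. In the data the estimated correlation within a list was as high as 0.595, for adipocyte markers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.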

Results

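Gene expression was measured in whole uteri of immature, ovariectomised C57BL/6 mice given sesame oil (vehicle) or 0.1 mg/kg 17-alpha-ethynylestradiol (EE), a synthetic oestrogen, by gavage. Uteri were taken 2, 8, 12 or 24 h after 1 dose, or 24 h after the last of 3 daily doses (the 3x24h schedule). Each of the 5 schedules had 2 EE and 2 vehicle arrays, and 1 further array was from 0 h, which made 21 arrays. The labels do not say that replicates are separate animals, so the p-values measure the spread between these samples. The number of arrays limits the precision: the median standard error (SE) of a log2 change was 0.35, so that a change of 1.63-fold equalled 2 SE.

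The series title names a uterine time course, and the comparison at each schedule asks which transcripts EE raised or lowered against vehicle at the same time. Of 5807 probe sets tested, 2013 passed at 1 or more schedules and 1373 of these passed at a single schedule. Each probe set that passed had both EE arrays above or both below the 2 vehicle arrays. The selection by p-value on the same arrays favours this separation, so it is no further support for the calls. Among probe sets not selected, chance gives it to 33.3%. Klf4, a zinc-finger transcription factor, was the 1 gene to pass at all 5 schedules and is named after its values were seen. It rose 3.40-fold at 2 h, 3.56-fold at 8 h, 3.51-fold at 12 h, 3.63-fold at 24 h and 4.70-fold at 3x24h. The call at 2 h was lost without vehicle replicate 1 (adjusted p = 0.151) or replicate 2 (adjusted p = 0.135). Of the genes to be named in any case, Muc1, which encodes an epithelial surface mucin, rose 2.91-fold at 12 h, 3.68-fold at 24 h and 6.93-fold at 3x24h. Its call at 12 h was lost without vehicle replicate 2 (adjusted p = 0.247), EE replicate 1 (0.173) or EE replicate 2 (0.161), and in 5 of 10 other planned settings (0.0534 to 0.0838). With the vehicle 3x24h arrays as control its log2 change at 12 h was 0.47 in place of 1.54 (adjusted p = 0.568). Vegfa, which encodes an endothelial growth factor, passed at none of the schedules (adjusted p = 0.99, 0.495, 1, 0.128 and 0.864 in time order). Its log2 change at 2 h was 0.99 (SE 0.95), and 3.07 without EE replicate 1 (adjusted p = 0.0455).

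**Figure D1:**
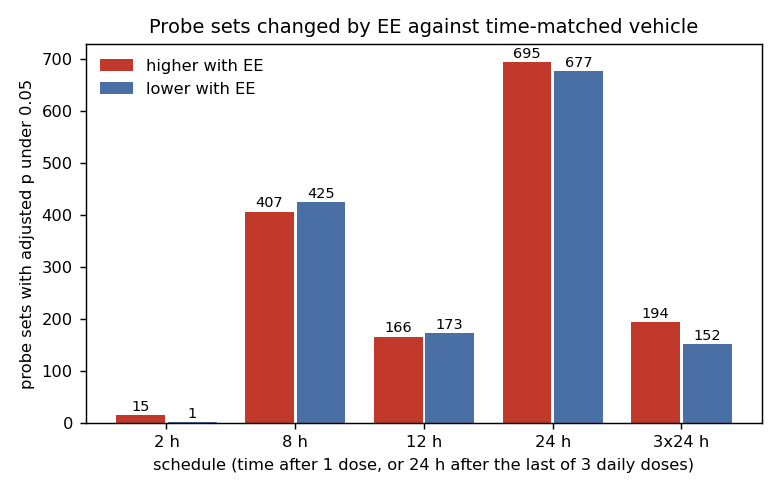
Number of probe sets with an adjusted p under 0.05 (vertical axis) at each schedule (horizontal axis), of 5807 tested, with bars for those higher and those lower with EE than with vehicle. The counts run from 16 at 2 h to 1372 at 24 h.

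Between the EE and vehicle arrays a control ratio also differed. The ratio of the BioB to the CreX hybridisation control, which are control transcripts added to the sample, was 0.0278 to 0.0453 on the 10 EE arrays. It was 0.0765 to 0.206 on the 8 single-dose vehicle arrays, 0.0535 to 0.0713 on the 2 vehicle 3x24h arrays and 0.159 on the 0 h array. Vehicle arrays were 3.40-fold above EE arrays (two-sided exact permutation test, p = 1.08e-05 over 184756 splits). Every EE change below was measured across this difference. The Gapdh 3′ over 5′ ratio, a sign of shortened RNA or complementary DNA, was 40.9 on EE 2 h replicate 1, 3.69 and 4.57 on the vehicle 8 h arrays and at most 1.39 elsewhere. The same ratio for actin was 12.4 on EE 2 h replicate 1, 3.30 and 3.78 on the vehicle 8 h arrays, 4.08 and 3.43 on the vehicle 24 h arrays against 2.40 and 1.83 on the EE 24 h arrays, and at most 2.60 on the others.

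**Figure D2:**
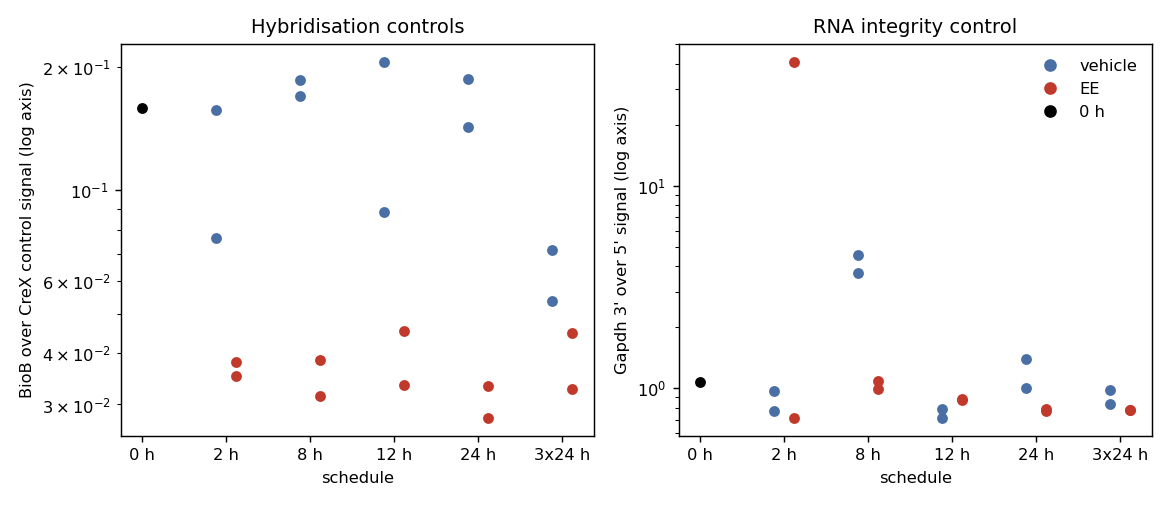
BioB over CreX control signal (left) and Gapdh 3′ over 5′ signal (right), both on log axes, for each of the 21 arrays by schedule, with EE, vehicle and 0 h arrays in separate colours. On the left the EE arrays lie at or below 0.0453 and the vehicle arrays at or above 0.0535, and on the right 3 arrays stand above 1.39.

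At 2 h after EE, Errfi1, which encodes an inhibitor of the epidermal growth factor receptor, rose 9.77-fold (log2 3.29, SE 0.50) from a signal of 1744 ± 113 to 17111 ± 2279 (SD, n = 2 each). Socs3, which encodes an inhibitor of cytokine signalling, rose 8.81-fold (log2 3.14, SE 0.30) from 562 ± 97.4 to 4974 ± 1072. Slc16a1, a monocarboxylate transporter, rose 5.46-fold and Ackr3, an atypical chemokine receptor, rose 5.66-fold. The other Ackr3 probe set changed by 1.39 on the log2 scale and did not pass. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose 3.83-fold on a probe set of shared sequence, so that its identity is uncertain. The Cdkn1a call was lost in 7 of 10 planned settings other than leaving out an array (adjusted p = 0.0505 to 0.638), and with the 50th percentile floor its log2 change was 0.64 in place of 1.94. The 1 probe set that fell was for Rgs2, a regulator of G-protein signalling, and it fell by 2.02 on the log2 scale. Rbm39, which encodes a splicing factor, rose 7.55-fold on 1 probe set, and the other Rbm39 probe set changed by 0.43 on the log2 scale and did not pass.

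In the limma test 16 of 5807 probe sets passed at 2 h, 15 higher and 1 lower, while 425 had an unadjusted p under 0.05 against 290 given by chance. The excess of rises was not stable. Falls outnumbered rises without EE replicate 2 or without vehicle replicate 2, and rises outnumbered falls without EE replicate 1 or vehicle replicate 1. The count was 4 without vehicle replicate 1, 5 without vehicle replicate 2, 46 without EE replicate 1 (the array with a Gapdh ratio of 40.9) and 51 without EE replicate 2. Without vehicle replicate 1 the call of Errfi1 (adjusted p = 0.151), Ackr3 (0.246), Cdkn1a (0.246) and Rgs2 (0.246) was lost. Without vehicle replicate 2 that of Errfi1 (0.142), Ackr3 (0.159), Slc16a1 (0.128), Cdkn1a (0.347) and Rgs2 (0.347) was lost. Without EE replicate 1 that of Ackr3 (0.102), and without EE replicate 2 that of Cdkn1a (0.127) and Rgs2 (0.143), was lost. The calls of Socs3 and Rbm39 passed with each of these 4 arrays left out. Rab14 was also taken by the rule at 2 h, and its call was lost without vehicle replicate 1, vehicle replicate 2 or EE replicate 1. Its log2 changes were then 1.96, 1.96 and 1.72. With the floor at the 10th percentile 7 of 10 named calls at 2 h were lost, and the Rgs2 call was lost in 5 of 10 planned settings (adjusted p = 0.0505 to 0.148). The calls of Rbm39 and Rgs2 were also lost with the vehicle 3x24h arrays as control (adjusted p = 0.123 and 0.105). Their log2 changes were 1.00 and -1.21 in that setting.

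At 2 h 5 lists passed camera, of which only that of immediate-early genes, which was higher, held with an estimated correlation. The calls of the known oestrogen-induced and nucleolar lists (higher) and of the ribosomal protein and epithelial lists (lower) were lost in that setting (adjusted p = 0.126, 0.675, 0.639 and 0.382). Of 14 measured immediate-early genes, 2 rose (Ier2 3.40-fold and Klf4 3.40-fold) and 6 rose when adjusted over the list alone, with a list median of 0.85 on the log2 scale (camera adjusted p = 7.26e-09). This call held with an estimated correlation (adjusted p = 0.00859). Of 11 measured genes known as oestrogen-induced in the uterus, Errfi1 and Cdkn1a rose, and 2 rose adjusted over the list alone (median 0.27, camera adjusted p = 0.00773, adjusted p = 0.126 with an estimated correlation). Of 29 ribosomal protein genes 28 were lower by any amount, with a median of -0.32 (camera adjusted p = 0.000269, adjusted p = 0.639 with an estimated correlation). The 18 epithelial markers, among them keratins and tight-junction genes, had a median of -0.41 (camera adjusted p = 0.00121, adjusted p = 0.382 with an estimated correlation) and the 31 nucleolar genes a median of 0.18 (camera adjusted p = 0.0359, adjusted p = 0.675 with an estimated correlation). In these 3 lists limma called 0 single genes, also when adjusted over the list alone, and 0, 1 and 7 genes had an unadjusted p under 0.05.

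Several list calls at 2 h rested on single arrays. Without vehicle replicate 1 the nucleolar list had an adjusted p of 0.198 and the epithelial list 0.256. Without EE replicate 2 the nucleolar list had an adjusted p of 0.885 and the known oestrogen-induced list 0.388. The ribosomal protein list was lost with quantile normalisation (0.125). The call of Ier2, whose product is an early nuclear protein, was lost with any of the 4 arrays left out (adjusted p = 0.0569 to 0.338), and that of Klf4 without vehicle replicate 1 (0.151) or replicate 2 (0.135).

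At 8 h 8 lists passed camera, of which only that of endoplasmic reticulum (ER) chaperones and the secretory pathway, which was higher, held with an estimated correlation. The nucleolar, translation, cytosolic chaperone, proteasome, sterol and known oestrogen-induced lists were higher and the list of the major histocompatibility complex (MHC) and the interferon response lower, but these 7 calls were lost in that setting (adjusted p = 0.0714 to 0.189). Mthfd2, a mitochondrial enzyme of folate metabolism, rose 13.8-fold (log2 3.79, SE 0.55) from 298 ± 20.4 to 4125 ± 279 (SD, n = 2 each). Plet1 rose 12.2-fold from 2145 ± 748 to 25378 ± 962, and Wdr74, a ribosome assembly factor, rose 11.8-fold. Sfrp2, which encodes a secreted Wnt modulator, fell by 3.22 on the log2 scale (SE 0.25) from 6999 ± 968 to 748 ± 15.7. Ypel3 fell by 3.40 on the log2 scale, Fmo1, a flavin-containing monooxygenase, fell by 3.21 and Dbp, a transcription factor driven by the circadian clock, fell by 3.68. With the vehicle 3x24h arrays as control the log2 change of Fmo1 was -1.34 and its call was lost (adjusted p = 0.0603). The largest rise, at least 18.5-fold, was of the tRNA synthetase gene Eprs on a probe set whose name ends in _i_at. Another Eprs probe set changed by 1.84 on the log2 scale. Ddx3x, an RNA helicase, rose 10.6-fold and G3bp2, a stress-granule protein, at least 17.8-fold, but the other probe sets for Ddx3x and G3bp2 changed by 0.13 and 0.06 on the log2 scale. Here and below, an "at least" marks a gene whose vehicle or EE arrays were both at or below the floor of 249.5 signal units.

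In the limma test 832 probe sets passed at 8 h, 407 higher and 425 lower, and 727 of them changed by 2-fold or more. Both vehicle arrays at 8 h carried the raised Gapdh ratio, and the count was 472 with that ratio as a covariate, 379 with the actin ratio as a covariate and 507 with the 3 arrays of raised Gapdh ratio left out and the vehicle 12 h arrays as control, 3 settings chosen after the data were seen. With those arrays left out 22 of 53 named calls at 8 h were lost, among them Wdr74 (adjusted p = 0.0554), Ddx3x (0.116) and Dbp (0.0751), whose log2 changes were 1.14, 0.65 and -2.09. With all 10 vehicle arrays as control 12 of the 53 were lost, among them Ddx3x (0.258) and G3bp2 (0.171). It was 504 without vehicle replicate 1, 467 without vehicle replicate 2, 245 without EE replicate 1 and 330 without EE replicate 2, and the genes named in the preceding paragraph passed with each of these 4 arrays left out.

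Of the 3 lists nearest to protein synthesis, that of cytosolic ribosomal proteins did not pass at 8 h (2 of 29 genes rose, 16 were lower by any amount, median -0.02 on the log2 scale, camera adjusted p = 0.421). Of 31 nucleolar and ribosome biogenesis genes 13 rose, 17 adjusted over the list alone (median 1.03 on the log2 scale, camera adjusted p = 7.26e-09, adjusted p = 0.118 with an estimated correlation). Among them were the assembly factors Rrs1 (5.91-fold), Nop56 (4.55-fold) and Mybbp1a (4.47-fold). Of 28 translation factors and tRNA synthetases 15 rose, 17 adjusted over the list alone (median 1.01, camera adjusted p = 1.08e-08, adjusted p = 0.0725 with an estimated correlation), such as the initiation factor subunit Eif2s2 (7.59-fold) and the synthetases Mars1 (6.36-fold) and Aars (6.30-fold). The elongation factor Eef2 and the synthetase Yars ran against that list, Eef2 lower by at least 7.94-fold, with its EE arrays at the floor, while Yars fell by 1.59 on the log2 scale. Yars was named after its values were seen. Eif6 was also among the largest rises that the rule took at 8 h. Its log2 change was 2.90 without EE replicate 1, where its call was lost. The Eef2 call was lost without vehicle replicate 2 (adjusted p = 0.153), EE replicate 1 (0.0981) or EE replicate 2 (0.0884), and that of Yars with any of the 4 arrays left out.

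Folding, degradation and sterol lists were also higher at 8 h. Of 34 genes of ER chaperones and the secretory pathway 11 rose, 12 adjusted over the list alone (median 0.57, camera adjusted p = 1.31e-07). Examples were the coat protein Sec13 (6.99-fold) and the secreted stress proteins Creld2 (4.65-fold) and Manf (4.28-fold). This call held with an estimated correlation (adjusted p = 0.0189). Of 17 cytosolic chaperones 7 rose, also 7 adjusted over the list alone (median 0.47, camera adjusted p = 0.00065, adjusted p = 0.0736 with an estimated correlation), such as Stip1 (7.34-fold) and Hsph1 (5.12-fold). With the 3 arrays of raised Gapdh ratio left out the calls of Sec13 (adjusted p = 0.563) and Stip1 (0.325) were lost, and with all 10 vehicle arrays as control likewise (0.112 and 0.0855). The small heat-shock gene Hspb1, named after its values were seen, fell by 0.99 on the log2 scale, a call lost without EE replicate 1 (adjusted p = 0.0811), with all 10 vehicle arrays as control (0.373), with the actin covariate (0.0578) and with the 3′ biased arrays left out (0.0802). With the vehicle 3x24h arrays as control the Hspb1 change turned to 0.28. Of 24 proteasome subunits 11 rose, 16 adjusted over the list alone (median 0.85, camera adjusted p = 7.26e-09, adjusted p = 0.0724 with an estimated correlation), with Psmb7 at 4.45-fold. Of 7 sterol synthesis genes 5 rose, also 5 adjusted over the list alone (median 1.70, camera adjusted p = 0.00402, adjusted p = 0.189 with an estimated correlation). These were Idi1 (4.32-fold), Sqle (at least 4.14-fold), Hmgcs1 (3.91-fold), Fdft1 (3.25-fold) and, named after its values were seen, Lss (2.13-fold). The other Lss probe set changed by 0.73 on the log2 scale and did not pass. Each of the 5 was lost without at least 1 array, up to an adjusted p of 0.312 for Lss without vehicle replicate 1, 0.152 for Idi1 and 0.0682 for Sqle without EE replicate 1, 0.0994 for Hmgcs1 without EE replicate 1 and 0.051 for Fdft1 without EE replicate 2.

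Of 23 genes of the MHC and the interferon response, 8 fell at 8 h, also 8 adjusted over the list alone (median -0.76, camera adjusted p = 0.00099, adjusted p = 0.0994 with an estimated correlation). The class II gene H2-Aa fell by 1.85 on the log2 scale from a signal of 21406 ± 829 to 5939 ± 224, while both other H2-Aa probe sets, of shared sequence, changed by 0.04 and 0.24. Ifit1, an interferon-induced gene, fell by 1.70 from 937 ± 42.8 to 237 ± 135, a call lost without vehicle replicate 2 (adjusted p = 0.0555) or EE replicate 1 (0.0943). The other Ifit1 probe set changed by -0.80 on the log2 scale and did not pass. Of 11 known oestrogen-induced genes 4 rose, 6 adjusted over the list alone (median 1.20, camera adjusted p = 0.000159, adjusted p = 0.0714 with an estimated correlation). They were Errfi1 (6.45-fold), Cdkn1a (at least 5.06-fold), Hbegf, a growth factor of the epidermal growth factor family (4.81-fold), and the ER chaperone Hspa5 (3.54-fold, probe set of shared sequence). The Hbegf call was lost with the vehicle 3x24h arrays as control (log2 0.79, adjusted p = 0.312). That of Hspa5 was lost with the 3′ biased arrays left out (log2 0.81, adjusted p = 0.0557). Hbegf was lost without vehicle replicate 1 (adjusted p = 0.0574).

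At 12 h 9 lists passed camera, of which only the ER list, which was higher, held with an estimated correlation. The nucleolar, translation, cytosolic chaperone, proteasome, known oestrogen-induced and respiratory chain lists were higher and the MHC and adipocyte lists lower, but these 8 calls were lost in that setting (adjusted p = 0.0736 to 0.762). Plet1 rose 6.22-fold from 3731 ± 800 to 22975 ± 1230 (SD, n = 2 each), Ddx39a, an RNA helicase, 5.76-fold and Slc35b1, a transporter of the ER membrane, 5.57-fold. Padi2, which converts arginine to citrulline in proteins, rose 7.17-fold from 577 ± 165 to 4058 ± 424, and Bop1, a ribosome assembly factor, rose 6.98-fold. Spock2, which encodes an extracellular proteoglycan, fell by 2.77 on the log2 scale (SE 0.31) from 5162 ± 1507 to 748 ± 147. Itih5, which encodes an inter-alpha-trypsin inhibitor chain, fell by 3.13. Hpgd, which inactivates prostaglandins, fell by 2.82 to a level at the floor, at least 7.06-fold.

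In the limma test 339 probe sets passed at 12 h, 166 higher and 173 lower, and 310 of them changed by 2-fold or more. The count fell to 60 without vehicle replicate 1, 70 without EE replicate 1 and 103 without EE replicate 2. Without vehicle replicate 1 the calls of Padi2 (adjusted p = 0.0653), Itih5 (0.0801) and Hpgd (0.114) were lost. Without EE replicate 1 those of Bop1 (0.0941) and Hpgd (0.077), and without EE replicate 2 those of Itih5 (0.0593) and Hpgd (0.0644), were lost. Plet1, Ddx39a, Slc35b1 and Spock2 passed with each of the 4 arrays left out. With the floor at the 10th percentile the count was 142 and 16 of 41 named calls at 12 h were lost.

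Of 31 nucleolar genes 7 rose at 12 h, 13 adjusted over the list alone (median 0.72, camera adjusted p = 1.02e-07, adjusted p = 0.126 with an estimated correlation), with Nop56 at 5.06-fold and Mybbp1a at 3.75-fold. Of 28 translation factors and tRNA synthetases 9 rose, 15 adjusted over the list alone (median 0.81, camera adjusted p = 7.24e-08, adjusted p = 0.0756 with an estimated correlation), with Eif2s2 at 4.83-fold. Of 34 ER genes 7 rose, 12 adjusted over the list alone (median 0.67, camera adjusted p = 1.63e-06), with Manf at 4.02-fold and Dnajb11 at 2.87-fold. This ER call held with an estimated correlation (adjusted p = 0.0263). Of 17 cytosolic chaperones 4 rose, 6 adjusted over the list alone (median 0.51, camera adjusted p = 0.0103, adjusted p = 0.126 with an estimated correlation), with Hsph1 at 3.23-fold. Hspb1 and the heat-shock gene Hspa1a, named after their values were seen, fell by 1.02 and 1.44 on the log2 scale. With the vehicle 3x24h arrays as control these changes were -0.097 and -1.20 and both calls were lost (adjusted p = 0.899 and 0.0717). The Hspb1 call was also lost with all 10 vehicle arrays as control (adjusted p = 0.11). Of 24 proteasome subunits 4 rose, 9 adjusted over the list alone (median 0.75, camera adjusted p = 1.2e-05, adjusted p = 0.126 with an estimated correlation), with Psmb7 at 3.97-fold. Without vehicle replicate 1 the calls of Nop56 (adjusted p = 0.0673), Mybbp1a (0.0758), Hsph1 (0.0625), Hspb1 (0.129), Hspa1a (0.152) and Psmb7 (0.113) were lost. Without EE replicate 1 those of Nop56 (0.0617), Hspb1 (0.114), Hspa1a (0.16) and Psmb7 (0.0944) were lost, and that of Hspa1a also without vehicle replicate 2 (0.151) or EE replicate 2 (0.181).

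Of 11 known oestrogen-induced genes 5 rose at 12 h, 7 adjusted over the list alone (median 1.15, camera adjusted p = 0.00065, adjusted p = 0.0736 with an estimated correlation). They were Errfi1 (4.28-fold), Cdkn1a (3.34-fold), Muc1 (2.91-fold), Hspa5 (2.32-fold) and, named after its values were seen, Odc1, which starts polyamine synthesis (2.07-fold). Each of the 5 was lost without at least 1 array, up to an adjusted p of 0.191 for Errfi1 and 0.287 for Hspa5 without vehicle replicate 1. Of 23 MHC and interferon genes 1 fell, H2-Aa by 1.72 on the log2 scale, and 5 fell adjusted over the list alone (median -0.56, camera adjusted p = 0.000984, adjusted p = 0.0994 with an estimated correlation). Both other H2-Aa probe sets changed by -1.31 and -1.67 on the log2 scale and did not pass. The H2-Aa call was lost without vehicle replicate 1 (adjusted p = 0.0522). Of 33 respiratory chain genes Ndufv2, a subunit of complex I, rose 1.87-fold, 1 adjusted over the list alone (median 0.33, camera adjusted p = 0.0225, adjusted p = 0.537 with an estimated correlation). That list was lost without vehicle replicate 1 (0.0532) or EE replicate 1 (0.0751), and Ndufv2 without those arrays (0.231 and 0.189) or EE replicate 2 (0.0666).

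At 12 h the 12 measured adipocyte markers had a median of -0.84 on the log2 scale (camera adjusted p = 0.0381, adjusted p = 0.762 with an estimated correlation), with 0 single calls by limma over all genes or over the list alone and 3 with an unadjusted p under 0.05. The call was lost without vehicle replicate 2 (0.791) or EE replicate 2 (0.455). At 24 h the list did not pass (median -1.49, camera adjusted p = 0.0578), and 3 members fell over all genes and over the list alone. These were Lpl, which encodes lipoprotein lipase and fell by 4.51 on the log2 scale, and the fat-cell hormone genes Adipoq, which fell by 3.01, and Retn, which fell by 2.77. The calls of Adipoq and Retn were lost with any of the 4 arrays left out (adjusted p = 0.0637 to 0.173 and 0.069 to 0.18). Against the mean of all vehicle arrays the median of the adipocyte list stood at -2.46 and -1.95 on the EE 24 h arrays and at -1.34 and -1.57 on the EE 3x24h arrays. It stood at 0.55 and -2.50 on the vehicle 3x24h arrays and at -0.47 and 0.89 on the vehicle 12 h arrays. On the same scale skeletal muscle markers stood at 1.38 on vehicle 2 h replicate 1 and 1.29 on EE 24 h replicate 1, and at most 0.18 on the other arrays.

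At 24 h 7 lists passed camera, all higher with EE: DNA replication, mitosis, glycolysis, translation, ER, proteasome and sterol synthesis. With an estimated correlation each of the 7 calls was lost (adjusted p = 0.121 to 0.537). Tk1, a thymidine kinase, rose at least 11.3-fold, from vehicle arrays at the floor to 2884 ± 796 (SD, n = 2). Padi2 rose 17.4-fold (log2 4.12, SE 0.47) from 580.2 ± 182 to 9926 ± 1833. Adh1, an alcohol dehydrogenase, rose 14.9-fold from 810 ± 412 to 11524 ± 3679, Car2, a carbonic anhydrase, 13.5-fold from 1670 ± 81.1 to 22858 ± 5412, and Mthfd2 at least 13.7-fold. Tgfbi, which encodes a matrix protein, fell by 4.07 on the log2 scale (SE 0.35) from 19526 ± 10250 to 1096 ± 291. Lpl fell by 4.51, beside the adipocyte medians given above, and Samsn1, an adaptor protein, fell by 4.11 on a probe set of shared sequence from a vehicle signal of 12364 ± 3943, the highest of the vehicle groups. The Samsn1 call was lost with all 10 vehicle arrays as control (adjusted p = 0.109), as was that of Adh1 (0.109), and with the vehicle 3x24h arrays as control those of Samsn1 (0.236) and Car2 (0.0539) were lost. The largest rise, at least 90.3-fold, was on a probe set for Tmem59 whose name ends in _i_at. The 3 other Tmem59 probe sets changed by -0.38, -0.44 and -1.83 on the log2 scale.

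In the limma test 1372 probe sets passed at 24 h, 695 higher and 677 lower, and 1163 of them changed by 2-fold or more. The count was 925 to 1527 with any 1 array left out, 249 with array weights and 1131 with the actin ratio as a covariate. With only the 4 arrays of the schedule limma called 0, and 1373 had an unadjusted p under 0.05. Of 59 named calls at 24 h, 31 were lost with array weights and 19 with all 10 vehicle arrays as control. The genes named in the preceding paragraph passed with each of the 4 arrays left out. EE 24 h replicate 2 stood apart from the other arrays, with a median correlation across probe sets of 0.771 and a correlation of 0.873 with its own replicate.

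Of 24 DNA replication genes 12 rose at 24 h, 13 adjusted over the list alone (median 0.97, camera adjusted p = 0.000122, adjusted p = 0.163 with an estimated correlation), such as the thymidylate synthase Tyms (5.29-fold), the ribonucleotide reductase subunit Rrm1 (3.01-fold) and the helicase subunit Mcm4 (2.75-fold). Of 24 mitosis genes 9 rose, 12 adjusted over the list alone (median 0.93, camera adjusted p = 0.00099, adjusted p = 0.201 with an estimated correlation), such as the topoisomerase Top2a (at least 4.74-fold), the spindle protein Nusap1 (at least 4.41-fold) and the kinase Cdk1 (4.0-fold). The calls of Rrm1, Mcm4 and Cdk1 were lost with array weights. Of 9 glycolysis genes 6 rose, also 6 adjusted over the list alone (median 1.02, camera adjusted p = 0.0133, adjusted p = 0.121 with an estimated correlation), such as Tpi1 (2.83-fold) and the hexokinase Hk1 (2.55-fold), both on probe sets of shared sequence. The glycolysis call was lost without vehicle replicate 1 (adjusted p = 0.0504) and with the vehicle 3x24h arrays as control (0.349). The calls of Tpi1 and Hk1 were lost with all 10 vehicle arrays as control (adjusted p = 0.166 and 0.129) and with the vehicle 3x24h arrays as control (0.0849 and 0.661).

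Of 24 proteasome subunits 10 rose at 24 h, also 10 adjusted over the list alone (median 0.86, camera adjusted p = 0.00697, adjusted p = 0.382 with an estimated correlation), with Psmb7 at 3.89-fold. Of 34 ER genes 10 rose, 13 adjusted over the list alone (median 0.63, camera adjusted p = 0.00773, adjusted p = 0.126 with an estimated correlation), with Sec13 at 4.26-fold. The calls of Psmb7 and Sec13 were lost with array weights (adjusted p = 0.0663 and 0.0734) and with the vehicle 3x24h arrays as control (0.179 and 0.0636), where their log2 changes were 0.74 and 1.14 in place of 1.96 and 2.09, and that of Sec13 also with all 10 vehicle arrays as control (0.0717). Named after their values were seen, the stress transcription factor Atf4 and the translocon subunit Sec61b fell by 0.97 and 0.95 on the log2 scale, and the co-chaperone Dnajb9 was lower by at least 2.31-fold. The other Dnajb9 probe set changed by -0.11 on the log2 scale and did not pass. Of 28 translation genes 7 rose, 11 adjusted over the list alone (median 0.62, camera adjusted p = 0.0297, adjusted p = 0.537 with an estimated correlation), with Eif2s2 at 3.16-fold. Named on the same ground, Eef2 was lower by at least 9.04-fold, with its EE arrays at the floor, and the translation factor Eif5a fell by 0.74. With all 10 vehicle arrays as control the changes of Atf4, Sec61b and Eif5a were -0.32, -0.14 and -0.05 (adjusted p = 0.474, 0.781 and 0.915), and with the vehicle 3x24h arrays as control they turned to 0.17, 0.15 and 0.13. Of 7 sterol synthesis genes 3 rose, also 3 adjusted over the list alone (median 1.19, camera adjusted p = 0.0133, adjusted p = 0.288 with an estimated correlation), namely Fdft1 (6.62-fold), Sqle (3.65-fold) and Lss (2.73-fold). The other Lss probe set changed by 0.95 on the log2 scale and did not pass.

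Without EE replicate 1 at 24 h the ER (adjusted p = 0.0683), proteasome (0.36), translation (0.323) and sterol (0.126) lists were lost, and without vehicle replicate 2 the translation (0.122) and sterol (0.064) lists. Without vehicle replicate 2 the calls of Sqle (0.119), Lss (0.0856), Eef2 (0.0547), Atf4 (0.16) and Dnajb9 (0.124) were lost. Without EE replicate 2 those of Atf4 (0.175), Dnajb9 (0.0647) and Sec61b (0.0861), without EE replicate 1 those of Dnajb9 (0.0521) and Sec61b (0.0517), and without vehicle replicate 1 that of Sec61b (0.168) were lost.

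**Figure D3:**
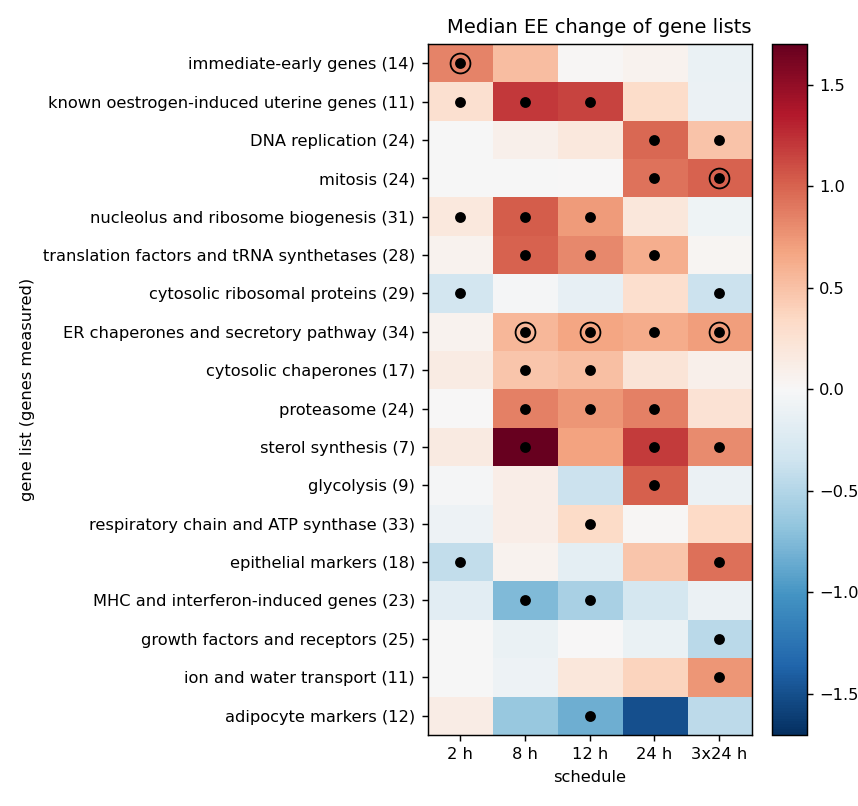
Median log2 change, EE minus vehicle, of the measured genes of 18 gene lists (rows, with the number of genes) at each of the 5 schedules (columns), as colour. A filled dot marks a list that passed camera with the preset correlation (37 of 185 tests) and a ring one that passed with an estimated correlation (5 tests).

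At 3x24h 8 lists passed camera, of which the mitosis and ER lists, both higher, held with an estimated correlation. The epithelial, DNA replication, ion transport and sterol lists were higher and the ribosomal protein and growth factor lists lower, but these 6 calls were lost in that setting (adjusted p = 0.126 to 0.759). Aoc1, a diamine oxidase, rose 97.6-fold (log2 6.61, SE 0.54) from 291 ± 100 to 29491 ± 3978 (SD, n = 2 each). Arg1, an arginase, rose at least 49.1-fold to 12399 ± 2555 and Alpl, an alkaline phosphatase, at least 36.6-fold to 9693 ± 4618. The matrix protease Mmp7 rose 19.1-fold, the complement regulator Cfi 18.5-fold, the collectin Sftpd 14.1-fold and Lrg1 13.0-fold. Tgfbi fell by 4.22 on the log2 scale (SE 0.35) from 36226 ± 7538 to 1919 ± 140, Plat, which encodes tissue plasminogen activator, fell by 4.46 and the nucleoside transporter Slc29a1 fell by 3.22. Prm1, which encodes a sperm protamine, fell by 5.17, the largest fall, on a probe set of shared sequence. Its signal was 25104 on vehicle replicate 1 and 5002 on replicate 2. Other testis transcripts were high on vehicle replicate 1 too, with Prm2 at 11459 and Ldhc at 6161, so the fall is not assigned to EE, and the call was lost with any of the 4 arrays left out (adjusted p = 0.0532 to 0.23).

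In the limma test 346 probe sets passed at 3x24h, 194 higher and 152 lower, and 320 of them changed by 2-fold or more. The count was 148 without vehicle replicate 1, 163 without vehicle replicate 2, 219 without EE replicate 1 and 126 without EE replicate 2. Apart from Prm1, the genes named in the preceding paragraph passed in each case. With the floor at the 10th percentile the count was 185 and 11 of 46 named calls at 3x24h were lost.

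Of 24 mitosis genes 7 rose at 3x24h, 11 adjusted over the list alone (median 1.00, camera adjusted p = 4.51e-10), such as Anln (6.52-fold), which acts in cell division, the spindle protein Prc1 (at least 7.65-fold) and Cdk1 (5.05-fold). The other Anln probe set changed by 1.57 on the log2 scale and did not pass. Of 34 ER genes 7 rose, 12 adjusted over the list alone (median 0.72, camera adjusted p = 3.54e-08), with the oligosaccharyltransferase subunit Rpn2 at 2.72-fold. Both calls held with an estimated correlation (adjusted p = 0.0373 and adjusted p = 0.0189). Of 18 epithelial markers 4 rose, 9 adjusted over the list alone (median 0.94, camera adjusted p = 3.52e-06, adjusted p = 0.163 with an estimated correlation). They were Muc1 (6.93-fold), Prom1 (4.89-fold), the desmosomal cadherin Dsc2 (3.8-fold) and the keratin Krt7 (5.09-fold), whose call was lost with any of the 4 arrays left out (adjusted p = 0.104 to 0.191). Of 24 DNA replication genes 5 rose, also 5 adjusted over the list alone (median 0.49, camera adjusted p = 0.000113, adjusted p = 0.163 with an estimated correlation). They were Rrm2 (5.52-fold, shared sequence), Tk1 (4.03-fold), Rrm1 (3.22-fold), Mcm4 (2.64-fold) and, named after its values were seen, the polymerase subunit Pola1 (at least 2.11-fold). Tk1 (adjusted p = 0.135), Mcm4 (0.0825) and Pola1 (0.136) were lost without vehicle replicate 2, and without EE replicate 2 (0.0702, 0.0806 and 0.299). Tk1 was also lost without EE replicate 1 (0.0933) and Pola1 without vehicle replicate 1 (0.144).

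Of 11 ion and water transport genes 4 rose at 3x24h, 5 adjusted over the list alone (median 0.76, camera adjusted p = 0.0247, adjusted p = 0.126 with an estimated correlation), such as the chloride channel Cftr (at least 4.28-fold) and Clca1 (8.59-fold). The potassium channel gene Kcnj8, named after its values were seen, fell by 2.42 on the log2 scale. Of 7 sterol genes 3 rose, also 3 adjusted over the list alone (median 0.80, camera adjusted p = 0.00207, adjusted p = 0.163 with an estimated correlation), namely Idi1 (6.29-fold), Sqle (3.99-fold) and Fdft1 (3.43-fold). Of 29 ribosomal protein genes 2 fell, Rps19 and Rplp2, both on probe sets of shared sequence, and 4 adjusted over the list alone (median -0.36, camera adjusted p = 0.013, adjusted p = 0.759 with an estimated correlation). Of 25 growth factor genes 2 fell, the matricellular gene Ccn2 and the binding protein gene Igfbp7, and 3 adjusted over the list alone (median -0.46, camera adjusted p = 0.0223, adjusted p = 0.312 with an estimated correlation). Without EE replicate 1 the ion (adjusted p = 0.0654), ribosomal (0.407) and growth factor (0.0919) lists were lost, and without vehicle replicate 2 the ribosomal (0.123) and growth factor (0.118) lists. Quantile normalisation also ended the ribosomal call (0.195). The calls of Rps19, Rplp2, Ccn2, Igfbp7 and Kcnj8 were lost with any of the 4 arrays left out, up to an adjusted p of 0.251, 0.218, 0.093, 0.156 and 0.142. Clca1 was lost without vehicle replicate 1 (0.0747) or EE replicate 2 (0.0566), Fdft1 without vehicle replicate 2 (0.0505) or EE replicate 1 (0.0578), Sqle without vehicle replicate 1 (0.113), vehicle replicate 2 (0.0933) or EE replicate 1 (0.139), and Idi1 without vehicle replicate 2 (0.163) or either EE replicate (0.0886 and 0.122).

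**Figure D4:**
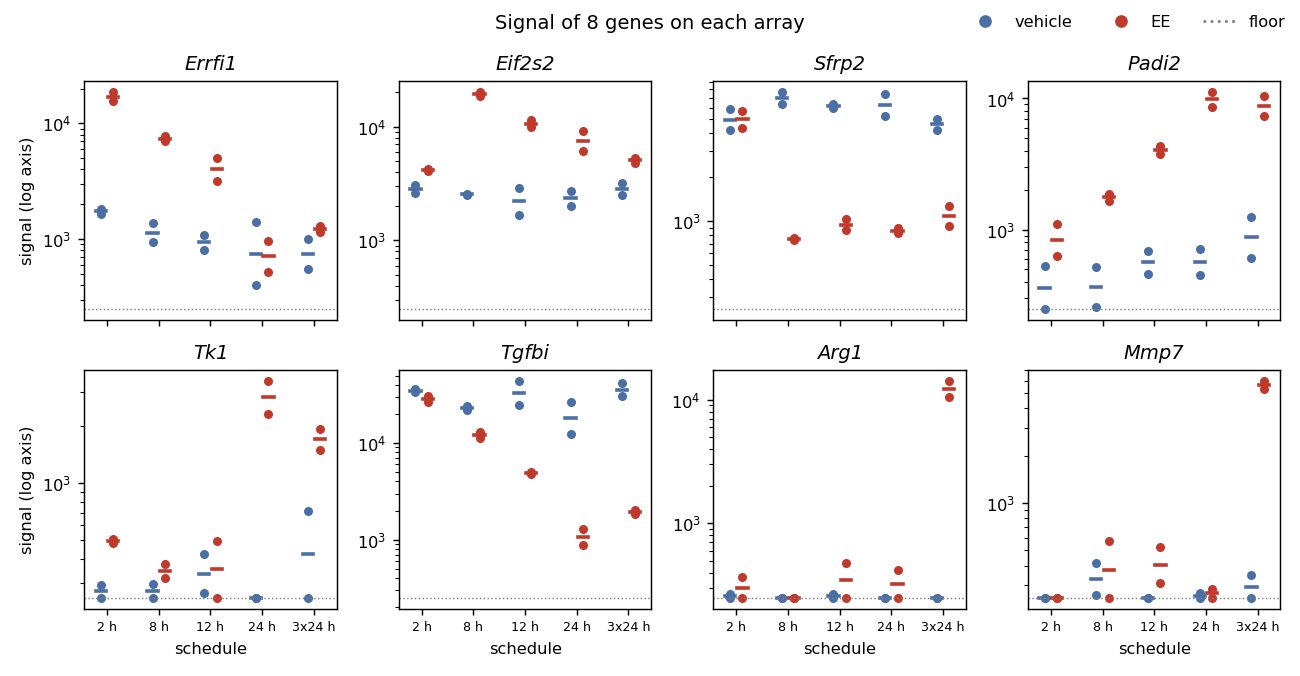
Signal on a log axis of Errfi1, Eif2s2, Sfrp2, Padi2, Tk1, Tgfbi, Arg1 and Mmp7 on each array by schedule, with points for arrays, short bars for the mean of the log2 values of each group of 2 and a dotted line for the floor of 249.5. Errfi1 was highest with EE at 2 h (17111), and Arg1 rose to 12399 at 3x24h with a vehicle level at the floor.

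The time course itself was tested as a difference of EE changes. The EE change differed among the 5 schedules for Errfi1 (adjusted p = 0.0329), which rose 9.77-fold at 2 h and did not pass at 24 h, and for Sfrp2 and Tgfbi (adjusted p = 0.00117 each). It also differed for Arg1 (adjusted p = 7.79e-05) and Cfi (4.2e-05), but did not pass for Klf4 (0.837) or Lpl (0.0931). With a moderated F test, 485 of 5807 probe sets passed, of which 479 also passed at 1 or more schedules. The count was 165 with the floor at the 10th percentile and 318 with the actin covariate. The count was 274 and 261 without vehicle 2 h replicate 1 and 2, 239 and 281 without EE 8 h replicate 1 and 2, 956 without EE 24 h replicate 1 and 311 without EE 3x24h replicate 2. Calls at 8 h and 12 h overlapped: 224 probe sets were called in the same direction at both, against 24.3 given by independence. At 8 h and 24 h 398 were shared against 98.3, and at 24 h and 3x24h 135 were shared in the same direction against 40.9, with 12 in opposite directions. Independence is a loose reference here, because each probe set has 1 estimate of spread for all schedules. The difference of the BioB to CreX ratio between EE and vehicle arrays is also common to the schedules.

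Both the 24 h and the 3x24h uteri were taken 24 h after the last dose. They differ in the number of doses and also in the time since the first dose, and the vehicle groups themselves differed, so a difference between the 2 schedules cannot be assigned to the number of doses alone. Arg1 rose at least 49.1-fold after 3 doses and had a log2 change of 0.37 after 1 dose, a difference of 5.25 (SE 0.44). Alpl, Aoc1, Cfi and Serpina1e, an antitrypsin gene on a probe set of shared sequence, had EE changes higher by 4.81, 4.78, 4.25 and 4.23 on the log2 scale after 3 doses. Mcpt4, a mast cell protease gene on a probe set of shared sequence, had log2 changes of 2.80 after 1 dose and -0.97 after 3, a difference of -3.77, and Phgdh, which starts serine synthesis, 1.32 and -2.32, a difference of -3.64. For Chn1 the change of -3.74 after 1 dose came with a vehicle signal of 10099 ± 832 at 24 h and 1076 ± 198 at 3x24h (probe set of shared sequence). The Phgdh call was lost without vehicle 3x24h replicate 1 (adjusted p = 0.0507) or EE 3x24h replicate 2 (0.0637). With array weights 6 of 12 named calls of this difference were lost, among them Serpina1e (adjusted p = 0.101), Chn1 (0.0936) and Phgdh (0.0677).

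In the limma test of this difference 505 probe sets passed, 259 higher and 246 lower after 3 doses. The count was 89 with array weights and 221 with the floor at the 10th percentile. Of these, 369 also passed at 24 h and not at 3x24h, 83 passed at 3x24h and not at 24 h and 18 passed at both. The count was 957 without EE 24 h replicate 1, 316 and 263 without vehicle 3x24h replicate 1 and 2 and 265 without EE 3x24h replicate 2. Of 29 ribosomal protein genes 6 had a lower EE change after 3 doses, 10 adjusted over the list alone (median -0.82, camera adjusted p = 0.00766, adjusted p = 0.766 with an estimated correlation). Of 23 MHC and interferon genes 3 had a higher EE change, also 3 adjusted over the list alone (median 0.88, camera adjusted p = 0.0268, adjusted p = 0.625 with an estimated correlation).

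The vehicle arrays were compared among the 5 schedules to show how far expression moved without EE. Samsn1 and Chn1, both on probe sets of shared sequence, differed among vehicle groups (adjusted p = 0.00582 and 0.00807). Samsn1 had a vehicle signal of 12364 ± 3943 at 24 h, against 1531 ± 1135 at 2 h and 1309 ± 57.8 at 3x24h (SD, n = 2 each). For Errfi1, Tgfbi and Aoc1 the vehicle groups did not pass (adjusted p = 0.333, 0.204 and 0.958). With a moderated F test 426 probe sets passed, and against the other vehicle groups 494 passed at 24 h, 221 at 3x24h and 24 at 8 h. The count of 426 was 207 and 213 without vehicle 2 h replicate 1 and 2, 203 without vehicle 24 h replicate 1, 181 without vehicle 3x24h replicate 2 and 246 without either EE 8 h array. It was 156 with the floor at the 10th percentile and 153 with the actin covariate.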

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

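All tests of explanations in this part were chosen after the result was seen, except that of the testis transcripts, whose prediction was written before the listed genes were tested though Prm1 had been seen.

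The first pattern is the EE change at 8, 12 and 24 h, which was measured across a 3.40-fold difference of the BioB to CreX ratio between vehicle and EE arrays, a signal outside the gene measurements. The vehicle 3x24h arrays have a ratio nearer to that of the EE arrays, so a run effect graded by the ratio would give them a good part of the EE change, yet the highest of 6 slopes of their difference from other vehicle groups on the EE change was 0.185. In Xist the vehicle 3x24h arrays lay within the range of the EE arrays, as such a run would have it, at 1041 to 1203 against 116 to 414 on the other vehicle arrays. The 18S rRNA signal, given below, was also higher on them than on the other vehicle arrays but did not group them with the EE arrays. Vehicle 3x24h replicate 2 lay above all EE arrays in it, and EE 2 h replicate 1 and EE 12 h replicate 2 lay within the range of the single-dose vehicle arrays. With the vehicle 3x24h arrays as control 19 of 53 named calls were lost at 8 h, 9 of 41 at 12 h and 25 of 59 at 24 h. With all 10 vehicle arrays as control 12 of 53, 6 of 41 and 19 of 59 were lost. The vehicle 24 h group also differed from the other vehicle groups at 494 probe sets. Such losses can thus come from differences between vehicle groups and do not by themselves mark a run effect. One shift shared by all EE arrays would give slopes near 1 between schedules, but the slopes of the 2 h and 3x24h changes on the 8 h change were at most 0.276. A run effect that differs by schedule, or that makes a small part of the change, stays open, since the ratio and treatment are confounded, and the effect of EE itself stays among the explanations as the design gives it.

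The second pattern is the large number of rises and falls at 8 h, where both vehicle arrays carried 3′ biased RNA. If that bias alone made them, they would vanish against other vehicle arrays on an EE array that took no part in the calls. The changes called without EE replicate 1 or 2 were measured on the array left out, with the vehicle 2 h and 12 h arrays as control. The median share kept was 0.697 and 0.604 for 129 and 180 rises and 0.623 and 0.589 for 116 and 150 falls, and 92.2% to 96% kept their direction. A vehicle 2 h or 12 h array put in place of the EE array gave medians of -0.0621 to 0.109 and a direction kept by 35.3% to 64%. Each such array was measured against the other vehicle 2 h and 12 h arrays, so its differences cancel over these arrays by construction. These values are therefore no independent level for comparison. Part of the change at 8 h may still come from the RNA quality, as the count was 472 with the Gapdh ratio and 379 with the actin ratio as covariate in place of 832, and 22 of 53 named calls at 8 h were lost with the 3′ biased arrays left out. A change of vehicle animals between 2, 8 and 12 h was not tested apart from this.

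The third pattern is transcripts of other tissues on single arrays. On the 0 h array 222 probe sets lay outside the range of the 10 vehicle arrays by over 2-fold, 157 higher and 65 lower, against 7 to 84 for single vehicle arrays. Ptgds had a signal of 45270 there against at most 563 on vehicle arrays, Oxt 33798 against at most 268, and 6 of 19 listed brain genes were over 2-fold above the range, such as Mag at 5855 and Gap43 at 11744, but the glial gene Gfap was at 128 and Ttr at 30.5. Mobp was at 15537 against at most 352.5 on vehicle arrays, and Stmn3 at 32241.5 against at most 917. Genes first seen on this array were left out of the brain list, and its bound was set after the array was seen. The median of the brain list was 0.916 on the log2 scale, below that bound of 1 for brain RNA in the sample. By this bound brain RNA in the sample cannot be told apart from another source. The list of nerve and Schwann cell markers, 10 measured genes of which the brain list holds 5, stood at 2.46 there against at most 0.474 on the other arrays, with S100b at 2668 and Sox10 at 1815 but Pmp22 at 3732 within the range of the vehicle arrays. A brain sample in place of uterus, which would put uterine genes over 3 log2 units lower, is argued against by a uterine list median of -1.77 with Tagln still at 15358. On vehicle 3x24h replicate 1 the 15 listed testis genes had a median of 1.45, with Prm2 at 11459 against at most 2002 on other vehicle arrays, a value in line with testis RNA in that sample, though no biological explanation was tested. Testis transcripts were also seen elsewhere: Prm2 was 4260 on the 0 h array, 4772 on EE 12 h replicate 2 and 3057 on EE 8 h replicate 2, and Ldhc was 2758, 1548 and 3407 on these. The list median was 0.439 on the 0 h array and at most 0.277 on the other arrays. On EE 24 h replicate 2 the list of ovary and oviduct markers, 10 measured genes, stood at 0.89 against at most 0.009 on the other arrays. Of these genes Hsd3b1 and Foxj1, named after their values were seen, rose at 24 h, with signals of 1069 and 1066 on EE replicate 1 and 3069 and 944 on EE replicate 2. The call of Hsd3b1 was lost without EE replicate 2 (adjusted p = 0.225) and that of Foxj1 was not (0.00919). Other lists were raised on EE 24 h replicate 2 too, with medians of 0.707 for granulocyte, 0.629 for lymphocyte and 0.532 for chemokine genes. The rise was thus not confined to ovary genes, while the adipocyte and MHC lists stood at -1.945 and -0.382. The array also had the highest median signal (785.6) and the smallest share of probe sets at or below the floor (25.92%). The ovary list did not pass at 24 h (camera adjusted p = 0.326), and no explanation was tested for this array.

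The EE change differed among the 5 schedules for 485 probe sets, and between 3x24h and 24 h for 505, by a test of the difference itself. Between 3x24h and 24 h the ribosomal protein list differed by a median of -0.82 on the log2 scale (adjusted p = 0.766 with an estimated correlation), and the MHC and interferon list by 0.88 (0.625 with an estimated correlation), so both calls were lost in that setting. Single genes with a higher EE change after 3 doses were Arg1 (5.25), Alpl (4.81), Aoc1 (4.78), Chn1 (4.28), Cfi (4.25) and Serpina1e (4.23). Those with a lower one were Tmem59 (-6.50), Mcpt4 (-3.77), Phgdh (-3.64), Stx2 (-3.48), Rps15 (-3.47) and Rgl1 (-3.33). The other Tmem59 probe sets went the other way, with changes of -0.38, -0.44 and -1.83 at 24 h and 0.37, 0.10 and 0.03 at 3x24h. For Chn1 the vehicle signal itself differed between these schedules, as given above. Without 1 array at a time the calls of Phgdh, Stx2, Rps15 and Rgl1 were lost: Phgdh without vehicle 3x24h replicate 1 (adjusted p = 0.0507) or EE 3x24h replicate 2 (0.0637), and Stx2 without vehicle 24 h replicate 2 (0.0545), either vehicle 3x24h array (0.0588 and 0.0525) or EE 3x24h replicate 2 (0.0717). Rps15 was lost without vehicle 24 h replicate 2 (0.08), either vehicle 3x24h array (0.0747 and 0.0604) or EE 24 h replicate 2 (0.0566). With array weights Serpina1e (0.101), Chn1 (0.0936), Phgdh (0.0677), Stx2 (0.101), Rps15 (0.139) and Rgl1 (0.193) were lost. Rgl1 was also lost without either vehicle 24 h array (0.083 and 0.1), either vehicle 3x24h array (0.0716 and 0.128), EE 24 h replicate 2 (0.14) or EE 3x24h replicate 1 (0.135). The ratio of the 18S rRNA control signal, EE over vehicle arrays, was 2.27 and did not pass (two-sided exact permutation test, p = 0.11). The vehicle arrays were not alike in it: the signal was 165 to 831 on the single-dose vehicle arrays, 1620 and 13129 on the vehicle 3x24h arrays and 365 to 4323 on the EE arrays.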

How the results depend on the processing

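Chosen only after the result was seen were the settings with the Gapdh or the actin 3′ over 5′ ratio as covariate, with 3′ biased arrays left out and with the vehicle 3x24h arrays as control. The cause was not tested for any change below, except that fewer arrays mean fewer degrees of freedom.

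The counts at 2, 8, 12, 24 h and 3x24h, among schedules, for 3x24h minus 24 h and among vehicle groups stayed within 1.5 times under the planned settings except as follows. Quantile normalisation gave 9 at 2 h. The floor at the 10th percentile gave 4 at 2 h, 142 at 12 h, 185 at 3x24h, 165 among schedules, 221 for the difference and 156 among vehicle groups, and the floor at the 50th gave 28 at 2 h. Array weights gave 37 at 2 h, 515 at 12 h, 249 at 24 h and 89 for the difference. All 10 vehicle arrays as control gave 64 at 2 h, 564 at 12 h and 523 at 3x24h. With only the 4 arrays of a schedule limma called 384 at 8 h and 0 at 2, 12, 24 h and 3x24h, where 592, 1058, 1373 and 1169 had an unadjusted p under 0.05. Of the settings added later, the Gapdh covariate gave 33 at 2 h and 472 at 8 h, the actin covariate 35 at 2 h, 379 at 8 h, 318 among schedules and 153 among vehicle groups, the vehicle 3x24h control 165 at 2 h, and omission of 3′ biased arrays 36 at 2 h and 507 at 8 h.

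Leaving out 1 array at a time gave 4 to 51 at 2 h, 245 to 945 at 8 h, 60 to 418 at 12 h, 925 to 1527 at 24 h and 126 to 423 at 3x24h. It gave 239 to 956 among schedules, 263 to 957 for the difference, 181 to 559 among vehicle groups and 31 to 40 list calls.

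Of 37 list calls over the 5 schedules, from 18 lists, 5 calls from 3 lists passed with an estimated correlation, and 30 passed in each of the 9 other planned settings run on lists without an array left out. A list fell short at 2 h for nucleolar genes with the 10th percentile floor (adjusted p = 0.0546) or a filter at 10 arrays (0.0658), at 12 h for MHC genes with the 50th percentile floor (0.0694) and at 3x24h for ion transport genes with that floor (0.0949) or filter (0.15). The ribosomal list was lost with quantile normalisation at 2 h (0.125) and 3x24h (0.195), the respiratory list at 12 h with the mean of all probe sets of a gene (0.0534) and the adipocyte list at 12 h with either other floor (0.0709 and 0.304) or the stricter filter (0.196), and with the actin covariate (0.0609). With the vehicle 3x24h control, lists were lost at 2 h for known oestrogen-induced (0.181), nucleolar (0.29) and epithelial genes (0.23), and at 24 h for translation (0.111), proteasome (0.0672) and glycolysis genes (0.349). Of 221 named calls, 120 passed in every planned setting that left out no array, apart from the 4 arrays of a schedule alone. With the vehicle 3x24h control the adipocyte list at 12 h reversed to 0.16 (adjusted p = 0.899), as did Aldoa (-0.27), Irf1 (-0.10), Eif5a (0.13), Atf4 (0.17) and Sec61b (0.15) at 24 h and Hspb1 (0.28) at 8 h.

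The labels do not pair EE with vehicle arrays by number. With a replicate block as a check, the counts were 14, 814, 355, 1369, 349, 495, 511 and 404 in the order above, with 37 list calls, and the correlation of replicate deviations was 0.0366, -0.00827, 0.0979, -0.00775 and 0.216 at the 5 schedules. Detection calls were not used here, and the number of arrays limits the precision.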

Other observations

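No test of an explanation is reported in this part, and the lists below, which did not pass camera, were chosen for description after their values were seen.

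Cell-cycle regulators of the G1 phase moved both ways. Of 18 measured genes 4 rose and 4 fell at 8 h (4 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.973). Rbl2, a pocket protein that represses cell-cycle genes, fell by 2.56 on the log2 scale (SE 0.35) at 8 h and at least 7.30-fold at 24 h, where its EE arrays were at the floor. Ccng2, a cyclin of resting cells, fell by 2.24 at 8 h, at least 4.72-fold. At 24 h 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.932). The kinase gene Cdk4 rose 5.43-fold from a signal of 1643 ± 805 to 8438 ± 1542 (SD, n = 2 each), and the kinase inhibitor Cdkn1c fell at least 10.6-fold from 2732 ± 947. The Cdk4 call was lost with all 10 vehicle arrays as control (log2 1.09, adjusted p = 0.149) and with the vehicle 3x24h arrays as control (log2 0.14, adjusted p = 0.813), and that of Cdkn1c with array weights (0.0592). The Ccng2 call at 8 h was lost with the 50th percentile floor (0.06).

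Complement genes rose and fell in the same samples. Of 12 measured genes 4 rose and 1 fell at 3x24h (4 and 2 adjusted over the list alone, camera adjusted p = 0.136). Cfb, a component of the alternative pathway, rose 12.2-fold from 1363 ± 545 to 15932 ± 1373, and the protease gene C1ra fell by 1.76 on the log2 scale, a call lost without vehicle replicate 1 (adjusted p = 0.0652) or EE replicate 2 (0.0726). At 24 h 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.984), and Cd59a, which blocks complement attack on cells, fell by 3.69 on the log2 scale. Among 13 genes of matrix proteases and their inhibitors 3 rose and 2 fell at 3x24h (4 and 3 adjusted over the list alone, camera adjusted p = 0.431), with Mmp7 19.1-fold higher and Mmp2 lower by 2.36 on the log2 scale, a call lost with all 10 vehicle arrays as control (adjusted p = 0.0891). Among 24 redox genes 2 rose and 4 fell at 24 h (3 and 4 adjusted over the list alone, camera adjusted p = 0.878), and the glutathione transferase genes moved apart: Gstm1 fell by 1.71 and Gstp1 rose 3.10-fold.

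The signal of Xist, a nuclear RNA of the inactive X chromosome, differed between the 10 EE and the 10 vehicle arrays (two-sided exact permutation test, p = 0.00661). EE arrays were 3.17-fold higher, at 129 to 2201. It was 1041 to 1203 on the vehicle 3x24h arrays, within the range of the EE arrays, and 116 to 414 on the other vehicle arrays. The lowest EE value was on EE 2 h replicate 1, the array with a Gapdh 3′ over 5′ ratio of 40.9.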
